A study of Mus musculus with 8 samples.

How the data were processed

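Whole testis RNA of mice on a mixed C3H/HeJ and C57BL/6J background was sequenced, per the labels. For each of the 8 libraries the authors deposited a gene table and a table of repeat families, without header lines. The genome build mm10 and the tools TopHat2 2.0.6, HTSeq 0.6.1 and Bowtie 1.0.0 are named in the submitters' processing notes, with no role given. The gene annotation, the strand setting and the treatment of reads that map to many copies of a repeat are not given in the sources used here, so families with similar sequence, paralogs and overlapping genes can share reads.

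The deposited values are log2 values. Every value equalled log2 of a whole count divided by a library factor, plus a pseudocount of 1. Counts recovered in this way were whole within 0.01 reads for 100% of values, and the factors equalled median-of-ratios factors recomputed over genes and families of each age. Each age was therefore scaled on its own, and levels are compared within an age. The lowest count was 6 in 7 libraries and 5 in 1, so a feature near silence in any library of an age is not listed, and genes silent in one genotype were not analysed here. One row of unassigned repeats, at most 0.011% of family reads, was left out. Gene symbols were looked up in GENCODE M21, whose build matches mm10, for the coordinates printed.

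The plan fixed before the data were examined used a count model. Because the deposited unit is log2, limma 3.58.1 in R 4.3.3 was used on the deposited values instead, with genes and families in one moderated fit (eBayes with a trend) and Benjamini-Hochberg adjustment over genes and over families separately, at 0.05. The joint fit was chosen after the data were seen, because the families alone gave an infinite prior; fitted alone they gave 239 calls against 106. At 20 dpp the fit held 2 mutant and 2 control libraries (2 residual and 5.21 prior degrees of freedom), and across ages 4 and 4 with age as a block. Nothing says that the libraries of a group came from separate animals, so p-values measure only the spread between these libraries. Fold changes are on the log2(value + 1) scale, which understates those of low genes.

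With 1 library per genotype, at 16.5 dpc and 10 dpp, no test was run. Ratios have exact conditional binomial 95% intervals, which cover counting error only, and a feature was listed at a ratio of at least 2-fold, an interval excluding 1 and at least 50 reads in both libraries together. Such ratios compare libraries, not genotypes.

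Before the data were examined, 18 gene lists and 13 repeat groups by name pattern were fixed. The satellite pattern met no family. Lists with at least 5 measured members were tested at 20 dpp with camera at a preset correlation of 0.01, adjusted over 17 lists. Without replicates, a list's median was placed among 10000 random lists matched on mean expression. Random lists draw genes independently, while genes of a cell type can move together, so the percentiles can overstate how unusual a median is. At 20 dpp the estimated correlation within lists ran from -0.11 for differentiating spermatogonia to 0.86 for Leydig cells. Named genes were the DNA methylation list, the 6 largest rises and 6 largest falls among genes that passed with at least 5 CPM in the higher group and separated libraries, leaving out predicted models, and the 2 members of lowest p in each list with a call. At single-library ages they were the 5 largest rises and falls with at least 100 reads, and families were the 8 largest rises and 4 largest falls with at least 50 reads on average, plus the 4 most abundant young LINE-1 and IAP families.

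The fits were tested on simulated counts with the real means and library sizes, 1 common spread for all features and changes planted in few of them. At 20 dpp, with 17181 simulated genes, 87% of genes changed 2-fold and 100% of those changed 4-fold were recovered. Across ages, with 16282 genes, 99% and 100% were, for changes planted alike at all 3 ages. Recovery of a change present at 1 age only was not simulated. Nor was recovery of shared changes beside many genes whose change varies with age. The rule for single libraries, tested on simulated pairs, listed 7 of 17509 unchanged genes at 16.5 dpc and 8 of 17176 at 10 dpp, and its intervals covered the true ratio for 95.2% and 95.6% of them. Python 3.11.15 with SciPy 1.17.1 gave intervals and exact tests. Alternatives covered scaling, pseudocount, filter, spread, replicates left out and blocks. Leaving out a 20 dpp library keeps 1 library in its group, so the residual spread then comes from the other group alone. Adjusted p-values, counts of calls and lost calls of such fits are not comparable with those of the main fit.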

Results

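Whole testis RNA was sequenced from mice carrying an IAP insertion, an endogenous retrovirus copy, in Dnmt3c. Dnmt3c encodes a DNA methyltransferase of the male germ line. Homozygous animals (IAP/IAP, called mutant here) were set against heterozygous animals (IAP/WT, called control) at 3 ages. The ages were 16.5 days post coitum (dpc), when male germ cells are arrested as gonocytes, and 10 and 20 days post partum (dpp), when the first wave of spermatogenesis reaches early meiosis and then late meiosis. There were 8 libraries in 6 groups, with 1 library per genotype at 16.5 dpc and at 10 dpp and 2 per genotype at 20 dpp. Reads on genes came to 74312625 in the mutant and 57166311 in the control at 16.5 dpc, and to 64884479 and 66947452 at 10 dpp. At 20 dpp they came to 127325877 and 95154320 in the mutants and 88996175 and 155742823 in the controls. Repeat families held between 2.34% and 5.52% of all counted reads. A value for Dnmt3c itself was not analysed here, so the genotype labels were not checked against the targeted gene.

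The first comparison asks which transposable elements differ between genotypes at 20 dpp. The largest rises among abundant families were in young LINE-1 elements, which still hold intact copies. L1Md_T rose by a log2 change of 3.10 ± 0.26 (SE), 8.57-fold, from 79962.7 ± 13967.9 normalised reads in the controls to 703190 ± 254561 in the mutants (SD, n = 2 each; limma adjusted p = 5.0e-04). L1Md_Gf rose 8.59-fold (adjusted p = 4.1e-04). L1Md_A rose 7.02-fold (log2 change 2.81 ± 0.70, adjusted p = 0.044), and its 2 mutant libraries differed 5.99-fold from each other. The call on L1Md_A was lost in limma without a trend (adjusted p = 0.123). Its log2 change was 2.98 without control replicate 1 and 2.64 without control replicate 2. It was 1.52 without mutant replicate 1 and 4.10 without mutant replicate 2. Young LINE-1 elements took 28.9% and 12.9% of family reads in the mutants, against 3.68% and 3.29% in the controls. The name pattern for this group also took in L1MDa, an older element, which did not pass the test (log2 change 0.47 ± 0.17), except with total gene reads as the scale (1.07, adjusted p = 0.0028).

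Endogenous retroviruses went both ways at 20 dpp, and whether shifts in cell shares account for this was not tested. In the same libraries 96 measured markers of spermatogonia and somatic cells had a median log2 change of 0.80 (highest 2.07, Eomes). The gene lists of pachytene and later spermatocytes and of spermatids had medians of -4.81 and -5.71. MMERVK10C-int, the internal part of an ERVK element, rose 4.65-fold (adjusted p = 0.0052) and its relative RLTR10B2 rose 5.11-fold (adjusted p = 5.0e-04). Among the abundant IAP families, IAPEY4_I-int rose 2.45-fold (adjusted p = 0.0058, and 0.0519 without a trend) and IAPLTR3-int fell by 2.43 on the log2 scale (adjusted p = 4.1e-04). IAPEY3-int had a log2 change of -0.42 that did not pass, and of -0.58 without mutant replicate 2. IAPEz-int had a log2 change of 1.61 ± 0.48 with a limma adjusted p of 0.077. Its mutant libraries differed 3.40-fold from each other, and its log2 change was 2.49 without mutant replicate 1 and 0.73 without mutant replicate 2. IAPEz-int passed with scaling by the families (adjusted p = 0.0080), with total gene reads (0.0073) and with families fitted apart from genes (1.2e-10). It also passed with the replicate number as a block. Among scarce families with large changes, MER91C, Charlie22a and Tigger20a rose 10.3-fold, 9.49-fold and 6.49-fold. MER91C lost its call without mutant replicate 2 (adjusted p = 0.0516), and Tigger20a without it (0.0537) or without control replicate 2 (0.062). IAPLTR3, MER92C, RLTR9A2 and RMER21B fell by 4.35, 3.90, 3.81 and 3.40 on the log2 scale, MER92C with a log2 change of -3.21 without mutant replicate 1 and -4.58 without mutant replicate 2.

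**Figure D1:**
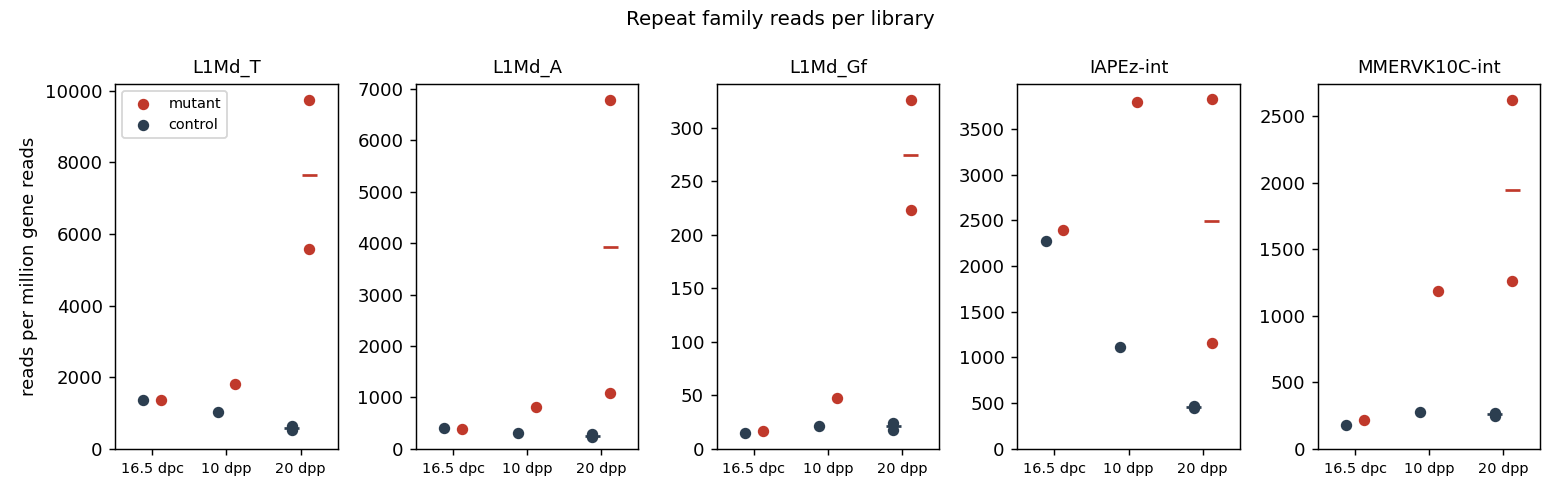
CPM of 5 repeat families, relative to gene reads (vertical axes, linear from 0), against age before or after birth. Each point is a library, red for mutant and dark for control, and short bars at 20 dpp are means of 2 libraries. At 20 dpp both mutant libraries lie above both control libraries in all 5 panels, and the mutant libraries of L1Md_A differ 5.99-fold on the normalised scale.

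In all, 106 of 888 families passed at 20 dpp, 42 higher and 64 lower. By group, 3 of 4 young LINE-1 families rose (median log2 change 2.95), 7 of 25 IAP families rose and 3 fell (0.39), and 4 of 13 MMERVK10C and RLTR10 families rose and 2 fell (0.47). Of the other LINE-1 families, 5 of 123 rose and 7 fell (0.22). Of 10 ETn and MusD families 1 rose and 1 fell (-0.33), and 0 of 8 MERVL and MT2 families passed (0.20). Of 120 MaLR families 4 rose and 8 fell (0.094, and -0.012 with scaling by the families), and of 46 VL30, MuLV and other ERV1 families 4 rose and 5 fell (0.13). Of 286 other LTR families 6 rose and 28 fell (-4.3e-04, and 0.047 with TMM scaling). Among SINEs, 1 of 15 B1 families and 2 of 5 B2 and B3 families rose, and 0 of 7 B4 and ID families passed. Of the remaining 226 repeats 5 rose and 10 fell (0.18). The split depended on scaling: with total gene reads it was 374 higher and 39 lower, and with scaling by the families themselves it was 28 and 66. Fitting the families apart from the genes gave 239 calls.

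The gene comparison at 20 dpp showed lower levels of transcripts of late meiotic and post-meiotic cells in the mutants. All 18 measured spermatid genes fell (median log2 change -5.71), for example Acrv1, an acrosomal protein (-8.54 ± 0.42), and Crem, a transcription factor of spermatids (-3.42 ± 0.16). Of 29 measured genes of pachytene and later spermatocytes 28 fell (median -4.81), among them Clgn, a chaperone (-5.79 ± 0.15), and Ropn1l (-6.51 ± 0.18). Of 24 genes of the piRNA pathway and transposon silencing 19 fell and 0 rose (median -2.22). Piwil1, the PIWI protein of pachytene spermatocytes, fell by 7.05 on the log2 scale and Pld6 by 3.90. The camera adjusted p was 1.3e-07 for spermatids, 9.5e-13 for pachytene spermatocytes and 3.0e-06 for the piRNA list, and the adjusted p was 0.383 for each with an estimated correlation. The pachytene list shares Piwil1 and Tdrd6 with the piRNA list.

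Early meiotic genes were divided: of 29 measured, 15 fell, 7 rose and 7 did not pass (median -0.58, camera adjusted p = 0.243). Syce1, of the synaptonemal complex, and Mlh3, of crossover repair, fell by 2.83 and 2.14. Spermatogonial lists lay higher. Of 17 genes of undifferentiated spermatogonia 9 rose and 1 fell (median 0.97, camera adjusted p = 0.019, adjusted p = 0.383 with an estimated correlation). Lin28a rose 2.53-fold, and Id4, a marker of stem cells, fell by 2.35. Of 9 genes of differentiating spermatogonia 7 rose and 1 fell (median 1.00, camera adjusted p = 0.027, adjusted p = 0.383 with an estimated correlation). Stra8, the retinoic acid target of meiotic entry, rose 3.06-fold and Dmrtb1, which governs the switch to meiosis, fell by 3.81.

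Markers of somatic cells of the testis moved in the same libraries. Of 23 Sertoli cell genes 21 rose and 1 fell (median 0.98, camera adjusted p = 1.2e-06, adjusted p = 0.383 with an estimated correlation). Wt1 rose 2.58-fold, and Cst9 fell by 2.06. Of 10 peritubular myoid genes 4 rose (median 0.83, camera adjusted p = 0.038, adjusted p = 0.539 with an estimated correlation), including Myh11 and Myl9 at 2.15-fold and 1.77-fold, both lost without control replicate 1 (adjusted p = 0.0841 and 0.148), and without a trend (0.0997 and 0.108), and Myl9 also without mutant replicate 1 (0.0529) and with scaling by the families (0.0541). Of 15 leukocyte genes 5 rose and 1 fell (median 0.50, camera adjusted p = 0.047, adjusted p = 0.539 with an estimated correlation). Fcer1g rose 2.30-fold, and Aif1, a macrophage gene, fell by 3.09. The myoid and leukocyte calls ended without mutant replicate 1 (adjusted p = 0.117 and 0.0897) and without control replicate 1 (0.0616 and 0.236). Of 11 Leydig cell genes 3 rose and 1 fell (median 0.49, adjusted p = 0.202), with Nr5a1 and Scarb1 1.83-fold and 1.64-fold higher. Of 11 endothelial genes 2 rose and 1 fell (median 0.30, adjusted p = 0.237), with Egfl7 1.98-fold higher and Vwf lower by a log2 change of -0.75. Egfl7 lost its call without mutant replicate 1 (adjusted p = 0.0625), and Vwf without mutant replicate 2 (0.138) or control replicate 1 or 2 (0.0855 and 0.11) or with total gene reads (log2 change -0.16, adjusted p = 0.606). Only 3 erythroid genes were measured, and none passed.

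The listed sex-linked genes rose together at 20 dpp. Of 20 X-linked genes 17 rose and 0 fell (median 1.15, camera adjusted p = 3.9e-07, adjusted p = 0.383 with an estimated correlation), with Taf7l and Scml2 3.30-fold and 4.07-fold higher. All 8 measured Y-linked genes rose (median 1.28, camera adjusted p = 2.6e-04, adjusted p = 0.383 with an estimated correlation), with Ddx3y and Eif2s3y 2.68-fold and 2.02-fold higher. Of 17 interferon response genes 8 rose (median 0.91, camera adjusted p = 0.0076, adjusted p = 0.383 with an estimated correlation), including Oas1a at 6.29-fold and Usp18 at 3.03-fold. Of 21 genes of the p53 and DNA damage response 12 rose and 3 fell (median 0.66, camera adjusted p = 0.038, adjusted p = 0.383 with an estimated correlation). Btg2 rose 2.48-fold and Mdm2 fell by 1.07, and the call ended without mutant replicate 1 (adjusted p = 0.0823). Of 17 imprinted genes 11 rose and 1 fell (median 0.67, camera adjusted p = 0.0040, adjusted p = 0.383 with an estimated correlation), with Meg3 and Impact 3.63-fold and 2.77-fold higher. In the same libraries the 96 measured markers of spermatogonia and somatic cells had a median log2 change of 0.80, beside the medians of 0.91, 0.66 and 0.67 of the interferon, p53 and imprinted lists and of 1.15 and 1.28 of the X-linked and Y-linked lists, and the differences from it were not tested.

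**Figure D2:**
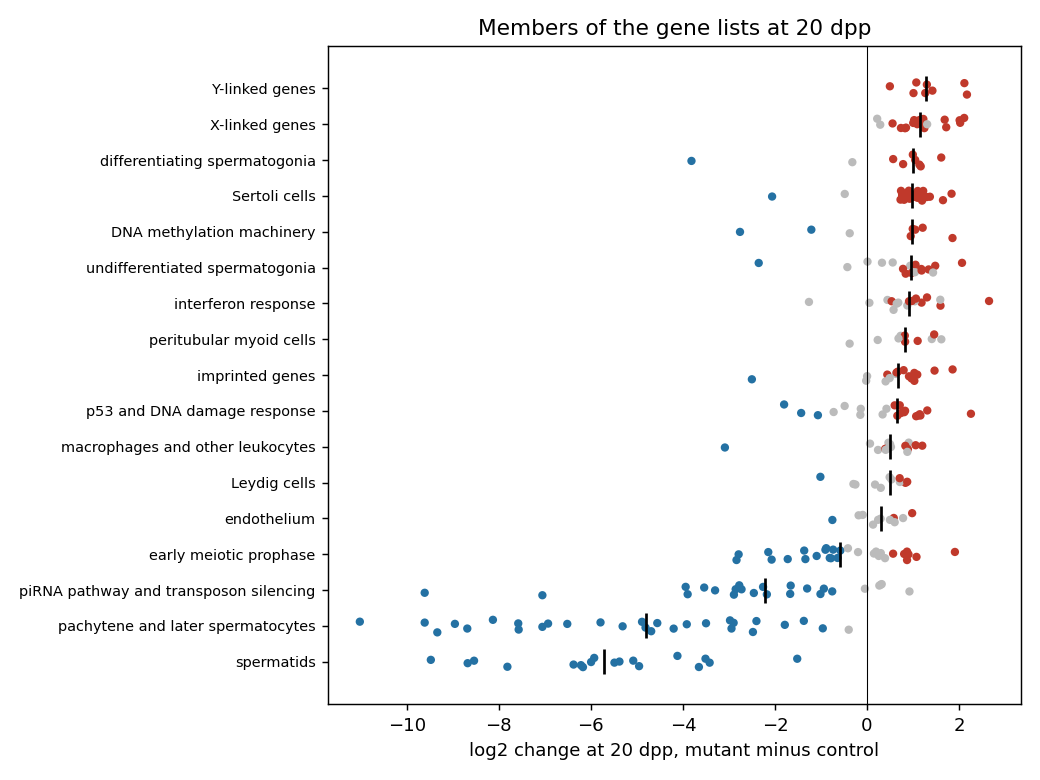
Log2 change at 20 dpp, mutant minus control (horizontal axis), of each measured member of 17 gene lists. Red points passed the test and were higher in the mutants, blue points passed and were lower, grey points did not pass, and black bars are list medians, from -5.71 for spermatids to 1.28 for Y-linked genes.

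The DNA methylation genes showed no common direction (8 measured, 5 rose, 2 fell, median 0.97, camera adjusted p = 0.243). Dnmt3a rose 2.07-fold and Dnmt3b 1.93-fold. The 96 measured markers of spermatogonia and somatic cells had a median log2 change of 0.80 in the same libraries. Dnmt3a (1.05), Dnmt3b (0.95), Tet1 (0.99) and Tet3 (1.21) lay near it and Tet2 (1.86) further above. The differences from that median were not tested. Dnmt3b (chromosome 2, 153649450 to 153687730 in mm10) lies beside its paralog Dnmt3c, and whether the 2 share reads was not tested. Tet2, Tet3 and Tet1, which oxidise methylcytosine, rose 3.63-fold, 2.31-fold and 1.99-fold, Tet1 losing its call without mutant replicate 2 (adjusted p = 0.158) or control replicate 1 or 2 (0.0743 and 0.0509) or without a trend (0.0552). Dnmt3l, the cofactor of de novo methylation, fell by 2.76 and Uhrf1, which recruits the maintenance enzyme, by 1.21. Dnmt1 had a log2 change of -0.37 and did not pass (adjusted p = 0.0578), except with scaling by the families (-0.48, adjusted p = 0.0417). Its log2 change without mutant replicate 2 was -0.55.

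The largest single rises were in Extl1, a glycosyltransferase gene (chromosome 4, 134356372 to 134383850 in mm10; 24.5-fold, from 96.3 ± 28.4 to 2460.1 ± 1095 normalised reads), Clca4 (21.8-fold), Pkhd1 (12.7-fold), P2rx1 (11.2-fold), the X-linked cyclin gene Ccnb3 (10.1-fold) and Cldn23 (9.68-fold). P2rx1 had a log2 change of 1.57 without mutant replicate 1 (adjusted p = 0.109) and lost its call without control replicate 1 or 2 (0.0679 and 0.0524). Without mutant replicate 2 P2rx1 had 5.41. Cldn23 had 4.91 without mutant replicate 1 and 1.64 without mutant replicate 2 (adjusted p = 0.0632) and lost its call without control replicate 1 (0.0547). Neither passed without a trend (adjusted p = 0.0944 for P2rx1 and 0.0769 for Cldn23) or with voom (0.0946 and 0.0975). The largest falls were in Adam3, a sperm membrane protein gene (-11.02 ± 1.44, from 94889.6 ± 12589 normalised reads in the controls to 152.5 ± 207.4 in the mutants), Pabpc2 (-10.68), Hrasls5 (-10.51), Cmtm2b (-10.30), Rbakdn (-10.05) and Fbp1 (-10.04). The mutant libraries differed in these genes. Without mutant replicate 1 the log2 changes lay between -13.74 for Adam3 and -11.69 for Fbp1. Without mutant replicate 2 they lay between -8.70 for Cmtm2b and -8.13 for Pabpc2. In total 10228 of 17194 genes passed, 4539 higher and 5689 lower, and 17 rose and 1461 fell at least 8-fold. With total gene reads as the scale, which moves the median of all genes by 0.60, the split was 8427 higher and 3795 lower. Counts adjusted over the list alone were the same as over all genes, except for DNA methylation (5 higher, 3 lower), Leydig cells (2 and 1), myoid cells (0 and 0), endothelium (0 and 0) and imprinted genes (12 and 1).

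At 10 dpp, with 1 library per genotype and no replicate check, some young LINE-1, IAP and MMERVK10C families were higher in the mutant library. Of 123 other LINE-1 and 119 MaLR families 0 were listed, and L1MDa had a log2 ratio of -0.071. IAPEz-int was 3.44-fold higher (95% interval 3.41 to 3.47), MMERVK10C-int 4.37-fold (4.30 to 4.44), L1Md_A 2.57-fold (2.53 to 2.61), L1Md_Gf 2.24-fold (2.11 to 2.39) and L1Md_T 1.77-fold (1.75 to 1.78). IAPLTR2_Mm was 4.81-fold higher, IAPLTR2a 2.23-fold and IAPEy-int 2.23-fold, and the scarce IAPA_MM-int 7.95-fold. IAPEY4_I-int, IAPLTR3-int and IAPEY3-int lay 1.25-fold, 1.10-fold and 1.21-fold higher. ERVB4_1-I_MM and ERVB4_1B-LTR_MM were 3.12-fold and 2.48-fold lower. By the rule for single libraries 15 of 823 families were listed, 13 higher and 2 lower. The same rule between the replicate libraries of 20 dpp listed 44 families in the mutants and 49 in the controls. Of 811 families measured at both 10 and 20 dpp, 13 were listed higher at 10 dpp and 41 rose at 20 dpp. The 5 that did both were IAPEy-int, L1Md_A, L1Md_Gf, MMERVK10C-int and RLTR10C, where independent lists would share 0.657. Families of similar sequence can share reads, so these 5 are not independent and the excess was not tested.

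Of 17376 genes at 10 dpp 154 were listed, 65 higher and 89 lower, and the same rule listed 1146 between the mutant and 949 between the control replicates of 20 dpp. Col19a1 (15.7-fold), Adtrp (11.8-fold), Rps15a-ps6 (6.01-fold, a pseudogene whose reads may belong to its parent gene), Spag16 (5.10-fold) and Capn11 (4.53-fold) led the higher genes. Spink8 (56.8-fold), Crisp1 (40.8-fold), Cldn8 (25.2-fold), Defb29 (19.7-fold) and Npy6r (18.3-fold) led the lower ones. Crisp1 and Defb29 are known from the epididymis, the duct attached to the testis, and a list of 27 duct epithelium genes, written after these were seen, had a median log2 ratio of -0.52, with 20 of 23 measured members lower. List medians were small at 10 dpp, and their percentiles ignore that genes of a list can move together. Sertoli cell genes stood at 0.15 (above all 10000 matched random lists), Leydig cell genes at -0.19 (below all of them), differentiating spermatogonia at -0.10 (percentile 0.26), endothelium at -0.11 (1.40), pachytene spermatocytes at -0.10 (1.73), undifferentiated spermatogonia at -0.095 (2.36), the piRNA list at -0.043 (2.81) and imprinted genes at -0.043 (3.77). The other lists lay between percentiles 8.43 and 87.7.

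At 16.5 dpc the young LINE-1 and abundant IAP families did not stand apart. L1Md_T was 1.00-fold (95% interval 0.992 to 1.01), L1Md_A 1.05-fold lower, L1Md_Gf 1.13-fold higher and IAPEz-int 1.05-fold higher (1.05 to 1.06) in the mutant library, and IAPEY4_I-int was 1.11-fold lower, IAPLTR3-int 1.14-fold higher and IAPEY3-int 1.17-fold higher. Of 806 families 4 were listed: ERVB4_1-I_MM (3.72-fold lower), ERVB4_1B-LTR_MM (2.18-fold lower) and, named after their values were seen, Tigger1a_Art (2.78-fold lower) and RLTR19D (2.20-fold higher). Of 17709 genes 130 were listed, 88 higher and 42 lower. The higher ones were led by structural RNA genes, Rpph1 (14.9-fold) and Rmrp (8.99-fold), with Lars2 (6.15-fold), the ribosomal precursor Rn45s (4.28-fold) and Hrk (3.45-fold). The lower ones were led by Cst9 (8.19-fold), Cst8 (4.03-fold), Fgf7 (3.64-fold), Rps15a-ps6 (3.21-fold) and Olfr1034 (3.12-fold).

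Alongside the structural RNAs at 16.5 dpc, germ cell lists stood higher in the mutant library. The median log2 ratio was 0.39 for the piRNA list, 0.34 for differentiating spermatogonia and 0.27 for early meiotic genes, each above all 10000 random lists, and 0.16 for undifferentiated spermatogonia (percentile 99.7). Leydig cell genes stood at 0.18 (above all random lists), Sertoli cell genes at 0.10 (99.9) and X-linked genes at 0.084 (99.6). Alb and Gc, known from the liver and named after their values were seen, were 2.49-fold and 2.25-fold lower in the mutant library. Leukocyte genes stood at -0.24 (below all random lists) and imprinted genes at -0.11 (0.050). The other lists lay between percentiles 8.33 and 95.6. All these percentiles treat the members of a list as independent.

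The last comparison asks for a genotype difference shared by the 3 ages, with 4 libraries against 4 and age as a block. No gene of 16282 and no family of 785 passed in limma (0 and 0 calls, and also 0 and 0 with voom). Differences that vary with age count as spread in this fit, so the 0 calls say nothing about changes at 1 age. At an unadjusted p under 0.05 there were 2325 genes and 42 families, and the lowest adjusted p was 0.243 and 0.703. Leaving out 20 dpp gave 4 genes and 6 families. The genes, named after their values were seen, were the cystatin gene Cst9 (chromosome 2, 148835147 to 148838738 in mm10; log2 change -3.54), Cst8 (-1.66), Snhg11 (-1.17) and Cst3 (0.67).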

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

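The tests on young LINE-1 elements and on Cst9 were chosen after the results were seen; the duct epithelium test was fixed before its values were seen, except that of Adam7 at 16.5 dpc. Several gene lists and families lay on opposite sides of 0 at different ages, in every library pair, and these differences between ages were not tested. The piRNA list had a median log2 ratio of 0.39 at 16.5 dpc and between -2.33 and -2.11 over the 4 library pairs of 20 dpp. Undifferentiated and differentiating spermatogonia stood at -0.095 and -0.10 at 10 dpp, and between 0.73 and 0.95 and between 0.88 and 1.04 at 20 dpp. Leukocyte and imprinted genes stood at -0.24 and -0.11 at 16.5 dpc and lay between 0.13 and 0.88 and between 0.53 and 0.88 at 20 dpp. ERVB4_1B-LTR_MM had log2 ratios of -1.12 at 16.5 dpc and -1.31 at 10 dpp and between 0.98 and 1.33 over the 20 dpp pairs. RLTR19D stood at 1.14 at 16.5 dpc and between -1.94 and -0.95 at 20 dpp, and RLTR9A3A stood at 1.14 at 10 dpp and between -2.24 and -1.22 at 20 dpp.

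Young LINE-1 families rose at 20 dpp, in libraries that lost late germ cell transcripts. A lower share of late germ cells would raise markers of the remaining cells as far. Of 96 measured markers of spermatogonia and somatic cells, 0 rose by as much as L1Md_T or L1Md_Gf (3.10 each), the highest being Eomes at 2.07. The same held with any 1 library left out, most narrowly without control replicate 1 (Eomes at 2.99 against a smallest rise of 3.28). Of 29 measured early meiotic markers, which are not among the 96, 0 rose by 2.81 or more, the highest being Prdm9 at 1.91. Ccnb3, which is in none of these lists, rose by 3.33, so single genes did rise as far. For L1Md_A the values do not decide: 0 markers rose by its 2.81 with all libraries, and 6 had changes at or above its 1.52 without mutant replicate 1. The choice among the scalings tried does not account for the rise of L1Md_T, whose lowest log2 change over the other scalings was 2.99 ± 0.23 (SE). These scalings moved the median of all genes by only -0.11 to 0.60, so none could have removed the rise. A larger error of scaling was not tested. A rise within 1 early germ cell type that gained share stays open, as does the genotype itself.

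Cst9 was lower in the mutant library or libraries at each age, and fewer Sertoli cells are argued against by the median of 20 other Sertoli markers, without the chromosome 2 genes Cst9, Cst12 and Defb36, which was 0.097 at 16.5 dpc and 0.14 at 10 dpp. Cst9 lies on chromosome 2 within 10 Mb of Dnmt3c, and a strain variant linked to the mutant allele is a candidate explanation in this mixed background. Without the cystatin genes, which prompted the test, 3 of 113 listed genes lay in that window at 16.5 dpc and 3 of 145 at 10 dpp, 2.07 and 1.61 times the share of other genes (Fisher's exact two-sided p = 0.18 and 0.44; with the cystatin genes 4.62 and 3.12 times). All 4 genes that passed across ages with 20 dpp left out (Cst3, Cst8, Cst9 and Snhg11) also lie in it, Snhg11 being the only one that is not a cystatin gene. Defb29 (chromosome 2, 152538714 to 152540098 in mm10), among the leading lower genes at 10 dpp, lies in it too. On the whole of chromosome 2 lay 22 of 117 listed genes at 16.5 dpc and 22 of 148 at 10 dpp, cystatin genes included. The share of other genes on that chromosome was not counted. The counts within the window are too few to decide, so a linked variant stays open. An effect of Dnmt3c on its neighbours stays open too and was not tested.

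Genes known from the epididymis led the lower genes of the 10 dpp mutant library, and duct epithelium carried into the 10 dpp control library is a candidate explanation. A list of 27 duct epithelium genes, which left out the genes already seen, had a median log2 ratio of -0.52 over 23 measured members at 10 dpp, below all 10000 matched random lists, with 20 lower; it stood at 0.0050 at 16.5 dpc and at 0.85 over 21 members at 20 dpp. Its most abundant members, Esrp1 and Epcam, were not lower (3544 against 3275 and 3481 against 3126 normalised reads), and their high level in both libraries would hide a small share. The random lists ignore that duct genes can move together. No other list holds any member of the duct list, and a genotype difference at this age stays open.

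No genes or families passed across ages in limma (0 and 0). With 0 calls, all 34 splits of the 8 libraries that could be fitted give at least as many by construction, so their count says nothing about chance. The highest of the other splits gave 11675 genes and 231 families. Only 2 other splits gave any gene; both set the 20 dpp mutants against the 20 dpp controls and kept the libraries of each other age together. With age as a block, such a split compares the 20 dpp libraries only, a structure of the samples that says nothing about the other ages.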

How the results depend on the processing

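Of the alternatives, TMM scaling, pseudocounts of 0.5 and 8, no trend, voom, families fitted apart and gene lists with a library left out were chosen after the data were seen. The planned count tests and the run without a filter were not run, because the unit is log2 and the tables are already filtered; the planned median-of-ratios scaling is that of the deposited values. No named gene or family that passed changed direction. Of all features that passed at 20 dpp, 598 genes and 4 families lay on the other side of 0 with total gene reads, 0 of them past the threshold there, and 0 under the other alternatives. Genes called at 20 dpp lay between 7672 and 12222 under every alternative except a minimum of 2-fold (6044). Families called, 106 in the main analysis, were 413 with total gene reads, 239 fitted apart from genes and between 43 and 108 with a library left out; fewer libraries lower the power, and otherwise the cause was not tested. With the replicate number as a block, 10059 genes and 104 families passed, no list call changed and IAPEz-int newly passed; the numbers share only a label (correlation of deviations 0.036). Across ages, leaving out 20 dpp gave 4 genes and 6 families, and families fitted apart gave 3; all other alternatives gave 0. At single-library ages, a 4-fold minimum listed 8 genes and 0 families at 16.5 dpc and 27 genes and 3 families at 10 dpp. A minimum of 20 reads listed 229 genes and 11 families at 16.5 dpc and 251 genes at 10 dpp, and one of 200 reads 28 genes, 2 families and 50 genes. With an estimated correlation 0 lists passed, at an adjusted p of 0.383 for the lists that had passed, or 0.539 for myoid cells and leukocytes. With fry, early meiotic genes passed (0.0205) and myoid and leukocyte genes did not (0.296). With a library left out, adjusted p lay between 1.1e-04 and 0.117 for myoid cells, 0.00535 and 0.236 for leukocytes, 0.0279 and 0.0823 for the p53 list, and 0.0127 and 0.923 for Leydig cells. Of 69 named genes and families, between 61 and 69 kept their side of the threshold under each alternative that measured all of them.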

Other observations

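At 20 dpp, of 648 X-linked genes with a position 452 rose and 26 fell (median log2 change 0.99), while of 15674 autosomal genes 3879 rose and 5367 fell (median 2.9e-04). Of 11 Y-linked genes with a position 9 rose and 2 fell, and 8 of those that rose are in the fixed list. Under other scalings the X and autosomal medians were 1.04 and 0.051 with TMM and 1.59 and 0.59 with total gene reads. With scaling by families they were 0.89 and -0.11. A scaling shifts all genes of a library alike, so it could not change the gap between the medians. The comparison of X-linked with autosomal genes was chosen after the data were seen. The autosomal genes include late germ cell genes that fell. The 96 measured markers of spermatogonia and somatic cells had a median of 0.80, and the X median was not tested against them.

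The 2 mutant libraries of 20 dpp differed 5.99-fold in L1Md_A, 3.40-fold in IAPEz-int and 2.15-fold in MMERVK10C-int, against 1.27-fold, 1.11-fold and 1.04-fold between the controls. For L1Md_T the values were 1.69-fold and 1.28-fold, and for L1Md_Gf 1.41-fold and 1.47-fold. ERVB4_1-I_MM was lower in the mutant libraries at each age, with log2 values of -1.90 at 16.5 dpc, -1.64 at 10 dpp and -0.86 at 20 dpp. Of 8 genes listed at both single-library ages, 5 had the same direction, and 4 of these (Cst8, Cst9, Cst11 and Tgm3) lie on chromosome 2.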
